A study of Mus musculus with 20 samples.

How the data were processed

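The series holds RNA sequencing of polyadenylated transcripts from 20 libraries of mouse embryonic fibroblasts, 4 of each of 5 genotypes. Per the labels, RNA was extracted with RNeasy midi columns and libraries were made with the NEBNext Ultra II kit. The authors deposited a table of CPM (reads per 1000000 reads assigned to genes) with a column for each library. Per the labels, the submitters' processing used HISAT2 2.0.4, SAMtools 1.3.1, HTSeq 0.6.1 and DESeq2 1.24.0 on GRCm38. The annotation release, the strand setting and any filter are not given.

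The deposited CPM values of each library are multiples of a smallest step, so whole read counts were recovered by dividing by it. All values lay within 0.01 of a whole read, and the largest distance was 0.0014. The recovered totals were 15570655 to 20519970 reads per library, so that 3 reads, taken as the floor, equal 0.146 to 0.193 CPM. Floors cover counting error only. The column of Control replicate 3 was scaled with the total of Control replicate 4, which makes its CPM 1.95% too low. The values were used as deposited, and rescaling this column was one of the alternatives. The 20 columns were assigned to samples through the column names in the labels, and no column was left over. Of 49671 gene IDs, 49326 matched GENCODE M21, which supplied positions, strands and exon overlaps, and 345 did not. Transcript length is that of each gene's longest transcript in GENCODE M21. In the table, 26 symbols had been turned into dates and were replaced through their IDs.

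The comparisons, the test, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. Values were transformed as log2(CPM + 0.5), and genes with at least 1 CPM in at least 4 libraries were kept, which left 13024. limma 3.58.1 in R 4.3.3 fitted a mean for each genotype over all 20 libraries, with 15 residual degrees of freedom and an intensity trend in the variance prior. Each knockout was compared with Control, the double knockout with each single knockout, and the Trp53 with the double knockout; the interaction is double minus both singles plus Control. P-values are two-sided and adjusted by Benjamini-Hochberg over genes within each of the 8 comparisons, with a threshold of 0.05. Simulated libraries took each gene's mean over all 20 libraries and its spread around the genotype means, with noise independent between genes. With known changes added to 200 of 13024 genes, the test recovered 14 to 26% of 1.25-fold, 64 to 68% of 1.5-fold and 88 to 90% of 2-fold changes. Of the calls, 4.17 to 6.25% were false. These shares leave out deviations shared between genes, such as those of Control replicate 4. The recovered shares hold for few changed genes, since the adjusted threshold is less strict where more genes change.

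Named genes are the 10 largest rises and 10 largest falls of each knockout against Control, and 5 and 5 in the other comparisons, among genes past the threshold with at least 5 CPM in the higher group and no overlap between the libraries of the groups. Predicted genes and pseudogenes were left out, the 3 targeted genes were always named, and up to 4 members with the smallest p were named for a gene list. Some genes that met this rule are not reported here. For the targeted genes a two-sided exact permutation test of 4 against 4 libraries was added, whose smallest p is 0.0286. Gene lists came from general knowledge, 33 in number, of which 30 had enough measured members to be tested; Zmat3, Cdkn1a and Trp53 are in none. List members were counted past the threshold over all genes and when adjusted over the list alone. limma's camera compared each list with the other genes at a preset correlation of 0.01 and again with an estimated correlation, adjusted over lists. Errors printed after CPM values are SD and those after log2 changes are SE. Summed markers are sums of CPM as deposited, without median-of-ratios scaling.

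The alternatives chosen beforehand were pseudocounts of 0.1 and 2, no filter on low values, a mean of at least 5 CPM, median-of-ratios scaling, the replicate number as a block, a fit of the compared libraries only, and leaving out each library of a comparison in turn. After the data were seen, 7 alternatives were added: leaving out each library outside a comparison in turn, rescaling Control replicate 3, leaving out Control replicate 4 and Trp53 knockout replicate 2 together, removing each library's trend with transcript length by lowess, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and a covariate for the letter A or G in the column names. The Control column names hold both letters, and the first was used, which is an assumption. The letter so taken is A for replicates 1 and 2 and G for replicates 3 and 4 of the Control, Cdkn1a and Trp53 groups, and A for replicates 1 and 3 and G for replicates 2 and 4 of the Zmat3 knockout; the double knockout has neither. The labels do not define it. Values within letters come from a fit with a mean for each genotype and letter, with 11 residual degrees of freedom. Replicate numbers do not pair the samples: of 40 pairs of libraries with the same number, 9 had deviations from their group means that correlated above 0.1. Tables were prepared with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and figures drawn with matplotlib 3.10.9.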

Results

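Polyadenylated RNA was sequenced from mouse embryonic fibroblasts transformed with the adenoviral oncoprotein E1A and with Hras carrying the G12V substitution, grown in 10% serum at 5% oxygen. The 20 libraries fall into 5 genotypes with 4 replicates each: Control (labelled wild type), Cdkn1a knockout, Zmat3 knockout, double knockout of Zmat3 and Cdkn1a, and Trp53 knockout. The labels do not say how the genes were disrupted, nor whether replicates are separate cell lines or separate cultures, so the errors below cover only the spread among these libraries. Reads assigned to genes ranged from 15570655 to 20519970 per library, and 3 reads corresponded to 0.146 to 0.193 CPM (reads per 1000000 assigned reads). Of 49671 genes in the table, 13024 were tested. The titles of the Trp53 group also name Zmat3, whereas its genotype field and the series text name Trp53 alone. The group is called the Trp53 knockout here. The series title places ZMAT3 and p21, the product of Cdkn1a, in the p53 network, and the comparisons ask which transcripts differ after loss of each gene, of both, and of p53 itself.

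Control replicate 4 and Trp53 knockout replicate 2 stood apart from their groups in a direction that followed transcript length. In Control replicate 4 the longest 20% of transcripts had a median of -0.60 on the log2 scale relative to the group, and the shortest 20% 0.32. The corresponding medians were -0.22 and 0.15 in Trp53 knockout replicate 2. The column names in the table carry an undefined A or G in the single and Trp53 knockouts, and both letters, in either order, in Control; those of the double knockout carry neither. Controls are called A or G here by the first of their 2 letters, and matching them with the A or G of a knockout is an assumption. Within Control, 357 genes differed between the letters, and 24 of 31 measured interferon-stimulated genes were higher in the A libraries (replicates 1 and 2) than in the G libraries (replicates 3 and 4), with a list median of 1.13. The G libraries include Control replicate 4, so the count of 357 cannot be told apart from its deviation. Control replicate 3 was also low for the interferon list, at a mean of -0.56 relative to the Control mean. No gene differed between the letters in the Zmat3 or Trp53 knockout, and 5 did in the Cdkn1a knockout. Values within letters are therefore given beside each comparison with Control; this split was made after the data were seen.

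The 3 targeted transcripts fell only in part in their own knockouts. Zmat3 (ENSMUSG00000027663, chromosome 3, 32334792 to 32366014, minus strand, GRCm38), which encodes a zinc finger RNA-binding protein induced by p53, averaged 291 ± 47.3 CPM (SD, n = 4) in Control and 205 ± 20.5 CPM in the Zmat3 knockout, 70.5% of Control (log2 change -0.49 ± 0.11 SE, limma adjusted p = 0.00203; exact permutation p = 0.0571). It averaged 214 ± 23.7 CPM in the double knockout (log2 change -0.43 ± 0.11, adjusted p = 0.00407; exact permutation p = 0.0857). Without Control replicate 4 the log2 changes of Zmat3 were -0.617 in the Zmat3 knockout and -0.559 in the double knockout. Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727, plus strand), which encodes a cyclin-dependent kinase inhibitor, averaged 741 ± 61.7 CPM in Control, 582 ± 18.9 CPM in the Cdkn1a knockout and 495 ± 40.2 CPM in the double knockout. Its change in the single knockout missed the threshold over all genes (-0.35 ± 0.07, adjusted p = 0.0808; without Control replicate 4 it passed, at -0.39 with adjusted p = 0.00636), although all 4 libraries lay below all 4 Controls (exact permutation p = 0.0286, the smallest that 4 against 4 allows). In the double knockout it fell (-0.58 ± 0.07, adjusted p = 2.03e-06; exact permutation p = 0.0286). Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873, plus strand) fell from 324 ± 22.0 to 85.6 ± 4.84 CPM in its own knockout (-1.91 ± 0.05, adjusted p = 3.04e-16; exact permutation p = 0.0286) and was at 105 to 106% of Control in the other knockouts. In the Trp53 knockout, Zmat3 (-2.44) and Cdkn1a (-2.19) fell on the log2 scale, so the amount of Zmat3 RNA does not decide between the title and the genotype field. Gene totals do not measure protein, and where the edits lie is not given.

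**Figure D1:**
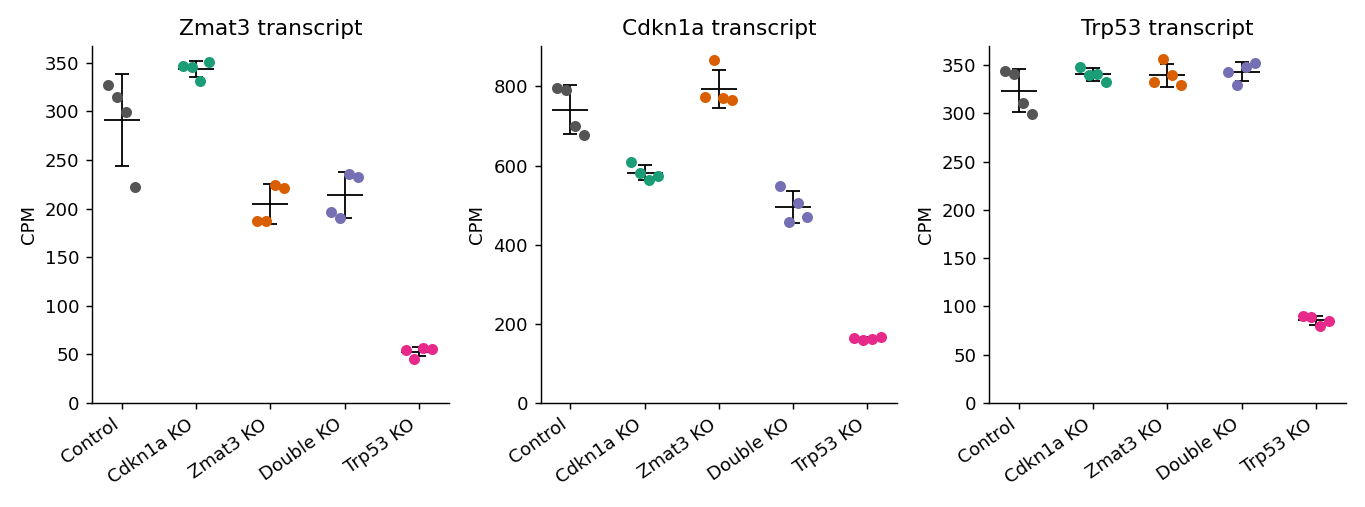
CPM of Zmat3, Cdkn1a and Trp53 in each library (points), with the mean and SD of the 4 libraries of each genotype. Each transcript was lowest in the Trp53 knockout, at 52.8 CPM for Zmat3, 162 CPM for Cdkn1a and 85.6 CPM for Trp53.

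Loss of Cdkn1a alone came with a fall of 5 transcripts. Of 35 splits of the same libraries, 2 gave at least as many genes, the real one included, so chance is not argued against. Serpinf1, the antiangiogenic serpin PEDF, fell from 8.21 ± 1.31 to 4.06 ± 1.11 CPM (SD, n = 4; log2 change -0.95 ± 0.13 SE). Plet1, a surface protein of placental and hair follicle progenitors, fell by 0.85 ± 0.13, and 13.4% of its exonic sequence overlaps other genes. Plau, the urokinase plasminogen activator, fell by 0.47 ± 0.06, from 238 to 172 CPM. Cotl1, an actin-binding protein, fell by 0.40 ± 0.07. The fifth gene, Gna15, a G protein subunit, fell by 0.92 ± 0.15 at a low level of 1.66 CPM in Control; it lies outside the naming rule and is named after its values were seen. All 5 fell, with adjusted p between 0.00356 and 0.0271 (limma with Benjamini-Hochberg), and none rose, with 1017 genes at an unadjusted p under 0.05. In the Zmat3 knockout the same 5 genes rose, Serpinf1 by 1.86, Plet1 by 1.12, Gna15 by 0.71, Plau by 0.70 and Cotl1 by 0.28.

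Among the fixed lists, secreted inflammatory and senescence-associated factors were lower after loss of Cdkn1a: of 12 measured, 1 fell (Plau) and 4 fell when adjusted over the list alone (camera adjusted p = 2.14e-05, 0.0199 with an estimated correlation). Epithelial markers were also lower as a list, with a median of -0.30 over 8 genes. None of these passed over all genes and 4 fell when adjusted over the list alone (camera adjusted p = 2.45e-06, 0.0135 with an estimated correlation). G2/M genes, which act in mitotic entry and chromosome segregation, had a median of 0.10 over 33 genes, of which 0 passed over all genes and 1 rose when adjusted over the list alone (camera adjusted p = 3.03e-06, and adjusted p = 0.419 with an estimated correlation). The 41 p53 target genes had a median of 0.08 and none passed by either adjustment (camera adjusted p = 0.0128, lost without any one of Control replicates 3 and 4 and Cdkn1a knockout replicates 1 and 2; adjusted p = 0.634 with an estimated correlation). The number of genes depends on single libraries: it was 3 without Control replicate 1 or 2, 8 without Control replicate 4, 2 without Cdkn1a knockout replicate 1 or 3, and 8 without Cdkn1a knockout replicate 2. It was 27 without both libraries that follow transcript length, 36 with DESeq2, 0 when only the 8 libraries compared were fitted, 0 among A libraries and 3 among G libraries. Summed cartilage and bone markers lay between 416 and 474 CPM, against 478 to 492 in Control. This gap is small beside the range of size factors, 1.0103 to 1.0374 here and 0.9461 to 1.0405 in Control, so it may not hold after scaling.

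Loss of Zmat3 raised transcripts of the extracellular matrix, which as a list passed camera at the preset correlation and not with an estimated one (adjusted p = 0.353). Col1a2, a chain of type I collagen (chromosome 6, 4504814 to 4541544), rose from 18.2 ± 2.72 to 92.3 ± 7.49 CPM, 4.99-fold (log2 change 2.32 ± 0.10 SE, n = 4). Bgn, the proteoglycan biglycan, rose from 161 ± 38.4 to 747 ± 133 CPM (2.22 ± 0.15). Lhx8, a LIM homeobox transcription factor, fell from 5.91 ± 0.123 to 0.510 ± 0.238 CPM (-2.70 ± 0.18). Among genes of at least 5 CPM whose libraries did not overlap, predicted genes left out, the largest rise was that of Pkp1, a desmosomal plakophilin, which went from 0.691 to 8.13 CPM (2.90 ± 0.22). Also among the 10 largest rises were the potassium channel Kcnk3 (2.15 ± 0.14), the matrix protein Tgfbi (2.09 ± 0.15), the collagens Col3a1 (2.08 ± 0.12), Col18a1 (2.01 ± 0.09) and Col6a3 (1.99 ± 0.25), the transcription factor Bcl11b (2.06 ± 0.14) and the urea transporter Slc14a1 (2.02 ± 0.13). After Lhx8, the largest falls were Kctd12 (-1.54 ± 0.17), the creatine kinase Ckb (-1.46 ± 0.12), Shtn1 (-1.46 ± 0.22), the cation channel Trpv2 (-1.43 ± 0.20), the transcription factor Tfap2a (-1.43 ± 0.21), the cornified envelope protein Sprr1a (-1.33 ± 0.22), the fibrillin Fbn2 (-1.30 ± 0.26), the keratin Krt19 (-1.18 ± 0.13) and the glycine cleavage enzyme Gldc (-1.17 ± 0.15). The adjusted p of these 20 genes lay between 8.15e-12 and 0.00123, and in each all 4 knockout libraries lay beyond all 4 Controls.

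Of 28 measured extracellular matrix genes, 21 rose and none fell in the Zmat3 knockout, with a median of 0.88; adjusted over the list alone, 21 rose and 1 fell (camera adjusted p = 1.51e-14, but adjusted p = 0.353 with an estimated correlation). Control replicate 4 had a mean of -0.53 for this list relative to the Control mean, against 0.13 to 0.23 in the other Controls, and without it 21 still rose and 1 fell. Of 18 TGF-beta response genes, 10 rose and 3 fell by either adjustment. Among them were Ltbp2 (a linear 2.36-fold rise), Id1 (0.60 on the log2 scale) and Id2 (-0.57 on the log2 scale). Its camera adjusted p of 0.0354 was lost without Control replicate 3 or Zmat3 knockout replicate 2, and the adjusted p was 0.398 with an estimated correlation. Among 19 integrins and cadherins, 9 rose and 2 fell by either adjustment, led by Itga3 (1.04), Cdh13 (1.73), Itga6 (0.86) and Itgb3 (0.63). Its camera adjusted p of 0.0182 was lost without Control replicate 4, and the adjusted p was 0.639 with an estimated correlation. Of 6 cartilage and bone markers, 4 rose and 1 fell by either adjustment, Col2a1 by 1.90 and Alpl by 1.65 among those that rose (camera adjusted p = 0.0182, and adjusted p = 0.353 with an estimated correlation). Summed markers of several cell types lay apart from Control without overlap: cartilage and bone ones between 678 and 721 CPM against 478 to 492, skeletal muscle ones between 6.77 and 8.65 against 3.75 to 5.60, macrophage and blood cell ones between 15.1 and 17.2 against 12.7 to 14.5, endothelial ones between 21.2 and 22.2 against 23.7 to 30.4, and adipocyte ones between 31.6 and 38.8 against 39.6 to 49.3. The gap for macrophage and blood cell markers is small beside the range of size factors, 1.0131 to 1.0278 here and 0.9461 to 1.0405 in Control. It may not hold after scaling.

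Several lists were lower after loss of Zmat3. Of 33 G2/M genes, 12 fell and none rose, with 14 falling when adjusted over the list alone, among them Bub1 (-0.41), Ccna2 (-0.29), Cdk1 (-0.39) and Ccnb1 (-0.26); the camera adjusted p was 0.0014, and the adjusted p was 0.549 with an estimated correlation. Of 26 Hox genes, which pattern the body axis and limbs, 10 fell, as did 10 adjusted over the list alone, where 1 rose. Examples are Hoxd13 (-1.04), Hoxd8 (-0.55), Hoxa11 (-0.45) and Hoxa9 (-0.32), and the camera adjusted p was 0.0169 (adjusted p = 0.543 with an estimated correlation). Of 33 ribosomal protein genes, 13 fell and 23 fell adjusted over the list alone (camera adjusted p = 3.27e-06, and adjusted p = 0.658 with an estimated correlation). Control replicate 4 had the highest mean of the Controls for this list, 0.57 against -0.20 to -0.18, and 7 of the 33 fell without it. Among p53 target genes 13 of 41 rose and 3 fell by either adjustment, with Ptpn14 (1.11), Ephx1 (0.95), Trp53inp1 (0.65) and Phlda3 (0.48) among those that rose. The camera adjusted p of 0.0497 was lost without Control replicate 3 or 4 and without Zmat3 knockout replicate 1 or 2, and the adjusted p was 0.658 with an estimated correlation. In all, 3747 genes changed, 1931 up and 1816 down, and 239 of those up and 52 of those down changed by at least 2-fold; 1419 changed when only the 8 libraries compared were fitted. Among A libraries 1432 genes changed and among G libraries 3033, with Controls taken by their first letter. Interferon-stimulated genes followed the letters of the Controls: 8 fell and 1 rose among A libraries, 24 rose among G libraries, and 3 rose and 1 fell in all libraries.

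**Figure D2:**
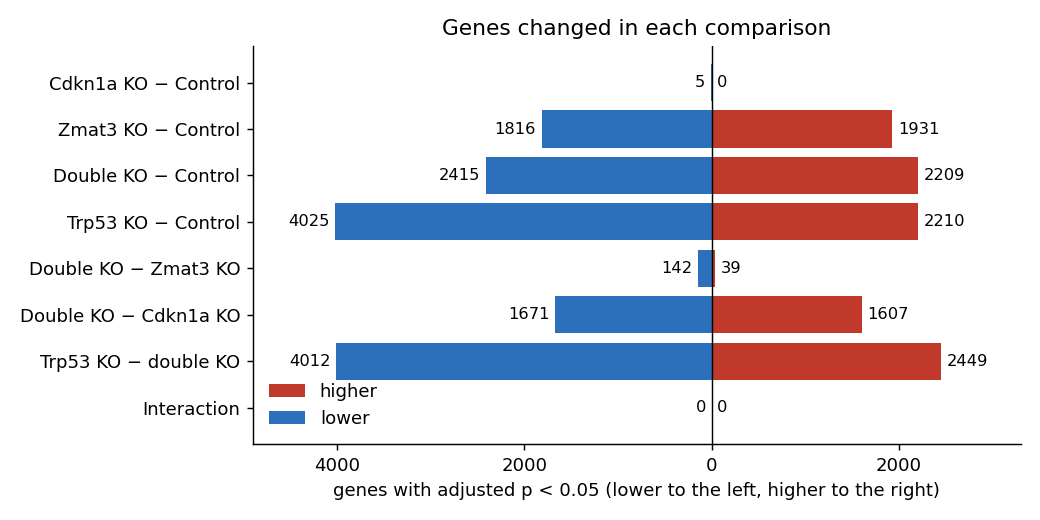
Number of genes that rose or fell (adjusted p under 0.05, limma) in each comparison of genotypes, out of 13024 tested. The count runs from 5 for the Cdkn1a knockout against Control to 6461 for the Trp53 knockout against the double knockout, and it was 0 for the interaction.

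In the double knockout, extracellular matrix and interferon-stimulated genes were higher than in Control, and Hox and immediate early genes were lower, by camera at the preset correlation; with an estimated correlation none of these 4 lists passed (adjusted p between 0.427 and 0.616). Bgn rose by 2.46 ± 0.15 on the log2 scale, to 872 ± 36.0 CPM (SD, n = 4). The other largest rises were those of the potassium channel subunit Kcnf1 (2.20 ± 0.24), Slc14a1 (2.15 ± 0.13), the protocadherin Pcdh1 (2.12 ± 0.11), Col3a1 (2.04 ± 0.12), Col1a2 (2.00 ± 0.10), Col18a1 (2.00 ± 0.09), the growth factor Pdgfb (1.98 ± 0.21), Bcl11b (1.96 ± 0.14) and the Ras association domain protein Rassf4 (1.94 ± 0.28). The largest falls were Lhx8 (-2.86 ± 0.18), Sprr1a (-2.44 ± 0.22), Trpv2 (-2.17 ± 0.20), Ckb (-2.13 ± 0.12), Prrg3 (-2.03 ± 0.24), Shtn1 (-1.98 ± 0.22), Krt19 (-1.89 ± 0.13), Kctd12 (-1.82 ± 0.17), Tfap2a (-1.78 ± 0.21) and the heparan sulfate endosulfatase Sulf1 (-1.72 ± 0.24). In all, 2209 genes rose and 2415 fell, of which 256 and 166 changed by at least 2-fold; 2071 changed when only the 8 libraries compared were fitted. Summed markers of other cell types also lay apart from Control without overlap: endothelial ones between 17.2 and 18.4 CPM against 23.7 to 30.4, adipocyte ones between 28.9 and 34.5 against 39.6 to 49.3, skeletal muscle ones between 5.76 and 7.63 against 3.75 to 5.60, and cartilage and bone ones between 628 and 661 against 478 to 492. The gap for skeletal muscle markers is small beside the range of size factors, 1.0114 to 1.0196 here and 0.9461 to 1.0405 in Control. It may not hold after scaling. Against the A Controls alone 2673 genes changed, and against the G Controls alone 5207.

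Of 31 interferon-stimulated genes, 22 rose and 2 fell in the double knockout, and 23 rose and 2 fell when adjusted over the list alone (median 0.88; camera adjusted p = 1.56e-06, and adjusted p = 0.616 with an estimated correlation). Oasl2, an antiviral protein, rose by 1.53, the transcription factor Irf9 by 1.08 and the antiviral membrane protein Bst2 by 1.04. The size depended on which Controls were used: 12 rose and 3 fell against the A Controls (median 0.39), and 27 rose against the G Controls (median 1.37). Of 28 extracellular matrix genes 20 rose and 3 fell, and 21 rose and 3 fell adjusted over the list alone (median 0.87; camera adjusted p = 6.78e-10, and adjusted p = 0.427 with an estimated correlation). Of 26 Hox genes 14 fell by either adjustment, with Hoxd13 (-1.56), Hoxa11 (-0.69), Hoxd8 (-0.61) and Hoxa10 (-0.50) as examples (camera adjusted p = 0.00101, and adjusted p = 0.427 with an estimated correlation). Of 15 immediate early genes, which respond to growth factors within minutes, 9 fell and 1 rose by either adjustment, with Atf3 (-1.47), Egr2 (-1.02), Ier2 (-0.75) and Junb (-0.71) as examples (camera adjusted p = 0.00112, and adjusted p = 0.427 with an estimated correlation). Ribosomal protein genes fell in 21 of 33 cases, in 23 adjusted over the list alone and in 13 without Control replicate 4 (camera adjusted p = 1.9e-06, and adjusted p = 0.616 with an estimated correlation). Of 33 G2/M genes 7 rose, such as Cenpf (0.72), Cdc25b (0.48) and Nek2 (0.35), and 2 fell, by either adjustment (camera adjusted p = 0.386).

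Loss of p53 lowered its known targets. Eda2r, a receptor of the tumour necrosis factor family (chromosome X, 97333840 to 97377216), fell from 114 ± 27.3 to 0.888 ± 0.288 CPM (log2 change -6.36 ± 0.15 SE, n = 4). Psrc1, a spindle protein, fell from 265 ± 25.6 to 9.67 ± 0.601 CPM (-4.70 ± 0.07). Pdgfb, the B chain of platelet-derived growth factor, rose from 8.34 ± 3.42 to 130 ± 5.45 CPM, 15.7-fold (3.97 ± 0.21). Ano3, an anoctamin membrane protein, fell from 48.7 ± 14.7 to 0.0677 ± 0.0973 CPM, under the floor of 3 reads, so its fitted change of -6.39 depends on the pseudocount. The other largest falls were Ddit4l, an inhibitor of mTOR signalling (-5.39 ± 0.11), the costimulatory ligand Cd80 (-5.37 ± 0.13), Trp53inp1 (-5.09 ± 0.13), Fam212b (-4.77 ± 0.12), the membrane protease St14 (-4.71 ± 0.16), the death-associated kinase Dapk1 (-4.40 ± 0.30) and the protease inhibitor Serpine2 (-4.10 ± 0.22). Among the other largest rises were Zbtb32 (3.50 ± 0.25), Trim71, a repressor of differentiation (3.28 ± 0.20), Mn1 (3.11 ± 0.14), Plvap (2.96 ± 0.15), the ATP-gated channel P2rx7 (2.93 ± 0.20), the troponin Tnnt2 (2.74 ± 0.16), the transcription factor Pou3f1 (2.68 ± 0.22) and the secreted hormone Stc2 (2.65 ± 0.14).

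Of 41 measured p53 target genes, 38 fell and 1 rose in the Trp53 knockout, and 39 fell and 1 rose adjusted over the list alone. The median was -1.93 (camera adjusted p = 9.3e-26, 0.0148 with an estimated correlation). Ak1 (-4.08) and Ccng1 (-3.93) were also among those that fell. Of 33 G2/M genes 20 rose and none fell by either adjustment, for example Cenpf (0.72), Nek2 (0.60), Cdc25b (0.57) and Cdc20 (0.44), with a camera adjusted p of 2.69e-06 (adjusted p = 0.411 with an estimated correlation). Of 26 Hox genes 18 fell and 1 rose by either adjustment, with Hoxd13 (-3.82), Hoxb9 (-2.18), Hoxc10 (-1.10) and Hoxc6 (-0.85) as examples (camera adjusted p = 5.42e-06, and adjusted p = 0.143 with an estimated correlation). Extracellular matrix genes divided, 5 rising and 12 falling by either adjustment (camera adjusted p = 0.867): Bgn rose by 1.94 and Loxl1 by 1.44, whereas Fbln5 (-2.04) and Col5a2 (-1.85) fell. Interferon-stimulated genes fell in 17 of 31 cases and in 19 adjusted over the list alone, and 1 rose by either adjustment (median -0.62, camera adjusted p = 0.102). Within letters, 24 fell and 1 rose among A libraries, and 14 fell and 4 rose among G libraries. Of the 33 ribosomal protein genes 1 rose in all libraries, 25 rose without Control replicate 4 and 0 without Trp53 knockout replicate 2 (median -0.01). In all, 2210 genes rose and 4025 fell, of which 223 and 856 changed by at least 2-fold; with median-of-ratios scaling 2916 rose and 3384 fell. Among A libraries 5038 genes changed and among G libraries 4728.

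**Figure D3:**
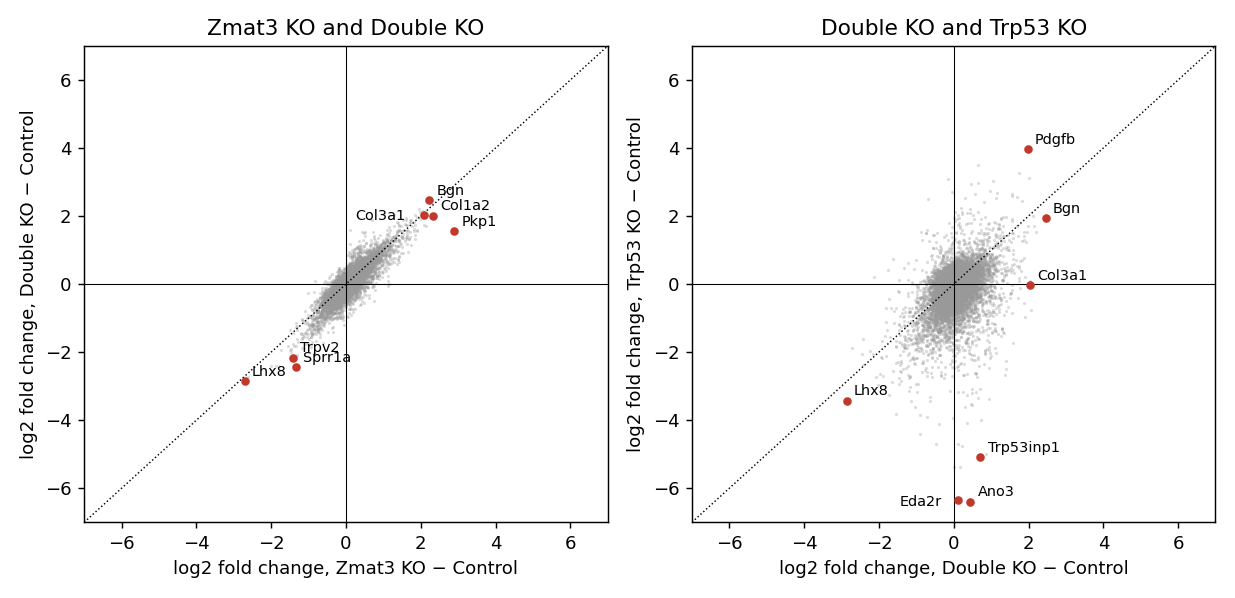
Log2 fold changes against Control, each point a gene: the Zmat3 knockout (x axis) against the double knockout (y axis) on the left, and the double knockout (x axis) against the Trp53 knockout (y axis) on the right, with some of the named genes in red. On the left Bgn lay at 2.22 and 2.46, and on the right Eda2r lay at -6.36 on the y axis.

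The double knockout shared most of its changes with the Zmat3 knockout. Of the genes that changed in both, 1517 rose in both and 1387 fell in both, where independent draws would give 328 and 337, and 4 moved in opposite directions. Both knockouts were compared with the same Controls, which by itself makes log2 changes correlate across genes: simulated unchanged groups gave a mean r of 0.44, from -0.33 to 0.88, against 0.88 here. Their covariance averaged 0.00791 and reached 0.0570, against 0.130 here. That they shared 0 calls says nothing about the shared genes, since groups without change have few calls to share. With the Controls divided so that each knockout had its own pair, r was 0.56 to 0.70 and 1836 to 2170 genes were shared. The Trp53 knockout shared fewer: 718 rises and 831 falls with the Zmat3 knockout (328 and 561 by independent draws), with 649 opposite, and 830 rises and 1293 falls with the double knockout (375 and 746), with 607 opposite. With divided Controls r lay between 0.00 and 0.36 for the former and between 0.10 and 0.43 for the latter. Of the 6235 genes that changed in the Trp53 knockout, 2123 (34%) changed the same way in the double knockout, and 831 of these also differed between the 2 knockouts. Genes are not independent replicates, so these correlations across genes carry no p.

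**Figure D4:**
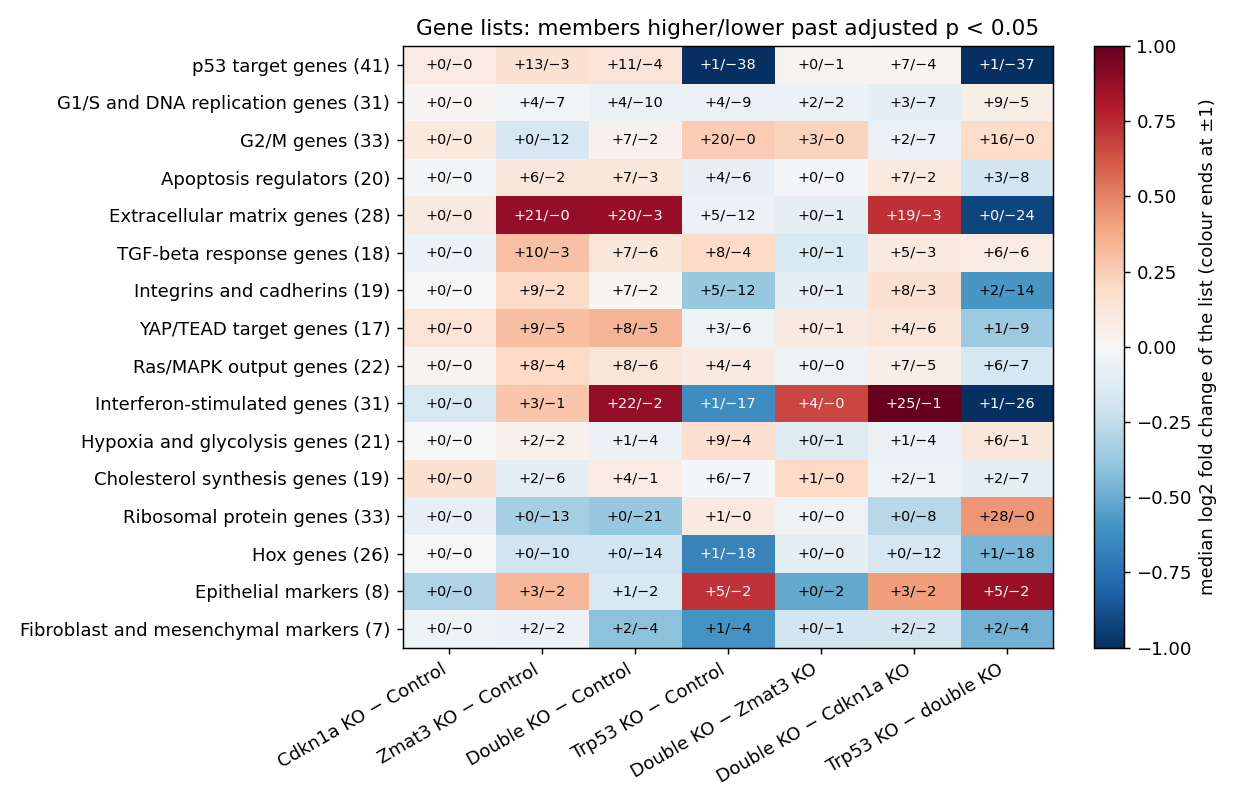
Median log2 fold change (colour) of 16 of the fixed gene lists in 7 comparisons, with the number of members that rose and fell in each cell and the number measured in brackets. Of 41 p53 target genes 38 fell in the Trp53 knockout, and of 28 extracellular matrix genes 21 rose in the Zmat3 knockout.

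Against the Zmat3 knockout, which asks what loss of Cdkn1a adds on that background, the double knockout had a higher G2/M list and a lower epithelial list by camera, with 3 of 33 and 2 of 8 genes past the threshold. The interferon-stimulated list was higher at the preset correlation only (adjusted p = 0.225 with an estimated correlation), with 4 of 31 genes. Oasl2 rose by 1.11 ± 0.27, the 2'-5'-oligoadenylate synthetase Oas1g by 0.90 ± 0.22, Bst2 by 0.82 ± 0.18 and Parp9 by 0.76 ± 0.18 (SE, n = 4). Among named genes of at least 5 CPM whose libraries did not overlap, the largest falls were Pkp1 (-1.34 ± 0.22), Plet1 (-1.18 ± 0.13), the anchoring filament protein Lad1 (-1.15 ± 0.16), Sprr1a (-1.11 ± 0.22) and the small heat shock protein Cryab (-1.06 ± 0.17). Serpinf1, Gna15, Plau and Cotl1, which fell with Cdkn1a loss against Control, also fell here (-0.53, -0.74, -0.45 and -0.55). Of 33 G2/M genes 3 rose (Cenpf by 0.48, Bub1 by 0.26, Ccna2 by 0.24), and 16 rose adjusted over the list alone (camera adjusted p = 3.9e-19, 0.0263 with an estimated correlation); without Control replicate 4, which takes part through the shared error estimate, 15 rose. Of 8 epithelial markers Krt19 and Epcam fell, and 4 fell adjusted over the list alone (camera adjusted p = 3.13e-05, 0.0263 with an estimated correlation). Interferon-stimulated genes rose in 4 of 31 cases, in 14 without Control replicate 4, and in 19 adjusted over the list alone, where 2 fell (camera adjusted p = 1.25e-12). Against the A libraries of the Zmat3 knockout 14 rose, and against the G libraries 10. Summed endothelial (17.2 to 18.4 CPM against 21.2 to 22.2) and cartilage and bone markers (628 to 661 against 678 to 721) were lower without overlap. So were epithelial ones, narrowly (453 to 483 against 484 to 536).

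In all, 39 genes rose and 142 fell between the double and the Zmat3 knockout (limma). The count moved with single libraries: it was 37, 59 and 53 without Zmat3 knockout replicates 2, 3 and 4, and 28, 90 and 60 without double knockout replicates 1, 2 and 3. It was 663 without Control replicate 4, 1061 when only the 8 libraries compared were fitted, 1042 without Control replicate 4 and Trp53 knockout replicate 2, and 435 with DESeq2. The interaction, which asks whether the double knockout differs from the sum of the single ones, gave 0 genes in limma, with 749 at an unadjusted p under 0.05, 0 in edgeR and 1 in DESeq2. The largest list difference there was that of the 31 interferon-stimulated genes (median 0.71), of which 0 passed over all genes and 16 rose adjusted over the list alone (camera adjusted p = 1.8e-19, and adjusted p = 0.562 with an estimated correlation).

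Against the Cdkn1a knockout, which asks what loss of Zmat3 adds, the double knockout repeated the rise of matrix genes, which as a list passed camera at the preset correlation and not with an estimated one (adjusted p = 0.298). Serpinf1 rose by 2.28 ± 0.13, the neurturin receptor Gfra2 by 2.25 ± 0.24, Rassf4 by 2.22 ± 0.28, Bgn by 2.18 ± 0.15 and Slc14a1 by 2.15 ± 0.13 (SE, n = 4). Under the same expression and overlap criteria, the largest falls were Lhx8 (-2.83 ± 0.18), the homeobox gene Emx2 (-2.23 ± 0.26), Trpv2 (-2.17 ± 0.20), Ckb (-1.98 ± 0.12) and Sprr1a (-1.91 ± 0.22). Of 28 extracellular matrix genes 19 rose and 3 fell, and 20 rose and 3 fell adjusted over the list alone (camera adjusted p = 1.55e-11, and adjusted p = 0.298 with an estimated correlation). Of 31 interferon-stimulated genes 25 rose and 1 fell, and 26 rose and 1 fell adjusted over the list alone (median 1.05; camera adjusted p = 1.55e-11, and adjusted p = 0.43 with an estimated correlation). Against the A libraries of the Cdkn1a knockout 24 rose and 1 fell, and against the G libraries 27 rose and 1 fell. Of 33 ribosomal protein genes 8 fell, 10 adjusted over the list alone and 29 without Control replicate 4 (camera adjusted p = 0.000153, and adjusted p = 0.78 with an estimated correlation). In all, 1607 genes rose and 1671 fell, 5678 changed when only these 8 libraries were fitted, and 5164 without Control replicate 4. Summed cell type markers also lay apart without overlap. Fibroblast (4660 to 5000 CPM against 3850 to 4070) and cartilage and bone ones (628 to 661 against 416 to 474) were higher. So were skeletal muscle (5.76 to 7.63 against 2.93 to 3.88) and epithelial ones (453 to 483 against 338 to 382). The sum of fibroblast markers does not stand for its typical member. The median over the 7 measured ones was lower in the double knockout, at 18.7 CPM against 38.4 in the Cdkn1a knockout. Endothelial (17.2 to 18.4 against 26.3 to 28.4) and adipocyte ones (28.9 to 34.5 against 36.4 to 48.5) were lower.

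**Figure D5:**
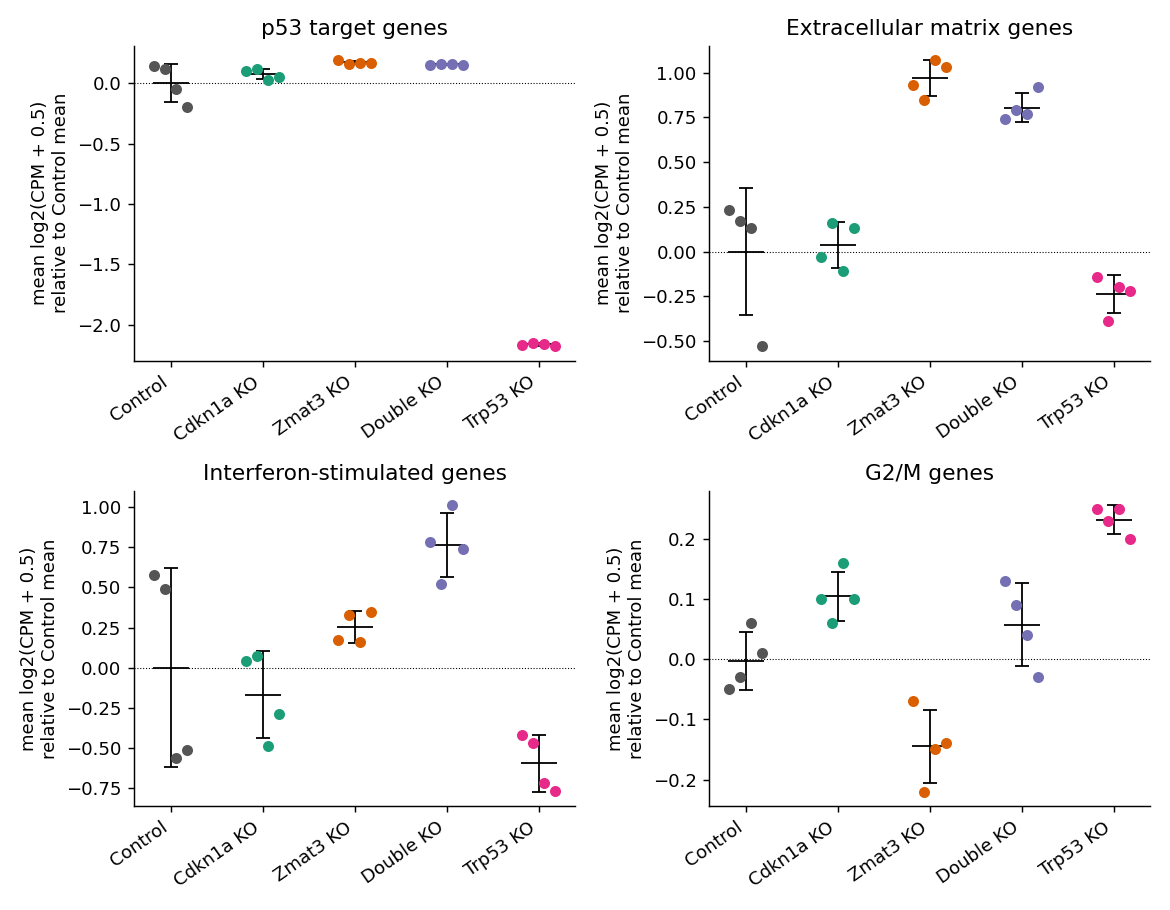
Mean log2 level of 4 fixed gene lists in each library (points) relative to the Control mean, with the mean and SD of each genotype. For interferon-stimulated genes Control replicates 1 and 2 lay at 0.58 and 0.49, replicates 3 and 4 at -0.56 and -0.51, and the double knockout libraries between 0.52 and 1.01.

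Against the double knockout, which asks what p53 loss changes beyond loss of these targets, the Trp53 knockout had lower p53 target transcripts. Matrix and interferon-stimulated genes were lower as lists at the preset correlation only (adjusted p = 0.405 and 0.533 with an estimated correlation). The imprinted gene Phlda2 rose by 3.19 ± 0.26 (SE, n = 4), Zbtb32 by 2.84, P2rx7 by 2.46 and Fbn2 by 2.35, and by these criteria the largest falls after Ano3 were Eda2r (-6.46), Trp53inp1 (-5.80), Ddit4l (-5.56) and Cd80 (-5.38). Of 41 p53 target genes 37 fell and 1 rose by either adjustment (camera adjusted p = 2.68e-26, 0.0135 with an estimated correlation). Of 28 extracellular matrix genes 24 fell by either adjustment, for example Col5a2 (-2.80), Thbs2 (-2.74), Col1a2 (-2.07) and Col3a1 (-2.06), with a camera adjusted p of 9.02e-08 (adjusted p = 0.405 with an estimated correlation). Of 31 interferon-stimulated genes 26 fell and 1 rose by either adjustment (median -1.48; camera adjusted p = 4.19e-07, and adjusted p = 0.533 with an estimated correlation). Among both the A and the G libraries of the Trp53 knockout 27 fell and 1 rose against the double knockout. Of 33 ribosomal protein genes 28 rose by either adjustment (camera adjusted p = 4.32e-08, and adjusted p = 0.533 with an estimated correlation). Without Trp53 knockout replicate 2, 20 of them rose, and 32 without Control replicate 4. Of 33 G2/M genes 16 rose by either adjustment (camera adjusted p = 4.3e-05, and adjusted p = 0.405 with an estimated correlation). In all, 2449 genes rose and 4012 fell, and 3116 rose and 3423 fell with median-of-ratios scaling. Summed cell type markers also lay apart without overlap. Fibroblast (2550 to 2930 CPM against 4660 to 5000) and myofibroblast ones (710 to 798 against 1070 to 1150) were lower in the Trp53 knockout. So were cartilage and bone (451 to 470 against 628 to 661) and macrophage ones (7.06 to 10.7 against 11.9 to 15.7). Skeletal muscle (19.1 to 22.5 against 5.76 to 7.63) and epithelial ones (675 to 817 against 453 to 483) were higher. Endothelial ones were higher too (25.1 to 27.3 against 17.2 to 18.4).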

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

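The tests of sequencing depth, of the length trend in Trp53 knockout replicate 2, of a wrong label from the Cdkn1a knockout, of the letters in the column names, of Control replicate 3, of the excess within letters, of the spread among Controls and of the remaining Cdkn1a transcript were chosen after the results were seen, as was 1 added condition named below. The tests of the length trend in Control replicate 4, of a wrong label from the other knockouts, of the ratio of effects and of other splits of the samples were written beforehand. A pattern in the Hox genes was examined first and then replaced by the interferon pattern, once the splits had pointed to the letters. By chance about 4 of 80 tests of library measures, transcripts and lists, and 14.8 of 295 tests of named genes, would place a library this far apart.

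Control replicate 4 and Trp53 knockout replicate 2 lay apart from their groups: the SD of all genes from the group median was 0.503 and 0.231, against 0.114 to 0.169 in the other libraries, and their deviations correlated across genes (r = 0.749). The trend with the length of each gene's longest annotated transcript is not the whole difference of Control replicate 4, whose SD remained 0.395 after its removal. Expressed transcripts can differ in length from the longest ones, so this does not exclude length itself as the whole cause. For Trp53 knockout replicate 2 the SD became 0.189, against at most 0.169 in the other libraries, which leaves open whether the trend is its whole difference. Low depth is argued against by 18.9 (Control replicate 4) and 19.3 (Trp53 knockout replicate 2) in units of 1000000 reads, each at or above the median of its group. That Control replicate 4 is a mislabelled Zmat3, double or Trp53 knockout library is argued against by its position of at most 0.19 on axes that run from the other Controls (0) to the Zmat3, double and Trp53 knockouts (1). A Cdkn1a knockout library in its place is not excluded, as that axis rests on 4 genes (position -0.22). Summed sex-linked identity genes stood at 156 CPM in Control replicate 4, against 505 to 596 in the other Controls. They stood at 386 CPM in Trp53 knockout replicate 2, against 466 to 674 in its group. Of these 6 genes 1 passed the filter, so the sums cannot tell other cells from the deviation that follows transcript length. RNA quality or library preparation, acting through transcript length alone or through more, may be a cause and stays open, as the labels give neither. No biological explanation was tested.

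Interferon-stimulated genes were higher in the double knockout than in Control, where the libraries differed among themselves. The length trend of Control replicate 4 is argued against as the source, because Control replicate 3, which lacks it, had a list mean of -0.56 as well. Column names of Control hold both letters, and Controls are called A or G by the first, an assumption. Against the A Controls alone 12 of the 31 members rose, where 22 did against all Controls, so the G Controls and a change in the double knockout cannot be told apart as the source, since the double knockout has no letters. A response to Cdkn1a loss that depends on Zmat3 stays open. If the letters match across groups, the mean rise from the Zmat3 to the double knockout exceeded that from Control to the Cdkn1a knockout. The excess was 1.08 among A and 0.28 among G libraries. Libraries of a group and letter, or of the double knockout, differed by up to 0.49. Across genes, the A minus G difference of the Cdkn1a knockout correlated at 0.22 with that of Control (0.46 without Control replicate 4). The correlation was 0.14 with the Trp53 knockout and -0.18 with the Zmat3 knockout. The matching therefore has little basis for the Zmat3 knockout, on which both excesses rest.

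Loss of Cdkn1a changed 5 genes against Control and 181 on the Zmat3 knockout (663 without Control replicate 4). The libraries that follow transcript length are argued against as the whole reason, because 27 against 1042 genes changed without both. Spread among the remaining Controls stays open. Leaving out those libraries does not remove it: the interferon-stimulated list means of the remaining Controls, relative to the Control mean, still ran from -0.56 to 0.58. The comparison on the Zmat3 knockout has no Controls in its contrast. The Cdkn1a transcript was higher in the single than in the double knockout, by 0.24 on the log2 scale (exact permutation p = 0.0286, two-sided), so a weaker loss of Cdkn1a in the single knockout may contribute. Dependence on Zmat3 cannot be told apart from this: over genes chosen on one part of the double and Zmat3 knockout libraries and measured on the rest, the median effect was 0.19 against Control and 0.43 on the Zmat3 knockout. The ratio was 0.44 (95% bootstrap interval over genes 0.38 to 0.50) and, by a condition added after the result was seen, 0.47 without Control replicate 4 (0.41 to 0.53), which does not lie wholly under the bound of 0.5. Both intervals take genes as independent, which they are not, so neither decides, and 85.6% of the genes had the same sign on both backgrounds.

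Other splits of the same libraries were counted for each comparison. Chance is argued against, not excluded, where only the real split, 1 of 35 and the fewest possible, reached the count. This held for the Zmat3 knockout (3747 genes, highest other split 95), the double knockout (4624, 17) and the Trp53 knockout (6235, 4216). The highest other split of the Trp53 knockout had Control replicates 1 to 3 and Trp53 knockout replicate 1 on the same side. It also held for the double against the Zmat3 knockout (181, 0) and the double against the Cdkn1a knockout (3278, 0). The same was true of the Trp53 against the double knockout (6461, 0). No adjustment was made over comparisons. Splits also cannot tell genotype from a difference between cell lines, which the labels do not describe. Chance is not argued against for the Cdkn1a knockout, where 2 of 35 splits gave at least the real 5 genes. The other split gave 252 and follows the letters, Control and Cdkn1a knockout replicates 1 and 2 against the rest, which points to a structure of the samples. With the letter as a covariate the count was 7. For the interaction the real count was 0, which all 100 regroupings must reach, so they say nothing about chance; the highest gave 2843.

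The remaining libraries far from their groups are listed by the gap to the nearest library as a share of the group's range. Reads assigned to genes set apart Cdkn1a knockout replicate 2 (0.911) and Trp53 knockout replicate 3 (0.840). Control replicate 4 stood apart in the number of genes with a read (0.928), the share of the 10 most abundant genes (0.875), the SD from the group median (0.950), the correlation with transcript length (0.895), the mean of extracellular matrix genes (0.872) and the mean of ribosomal protein genes (0.972). Trp53 knockout replicate 2 stood apart in the mean of ribosomal protein genes (0.844) and in the Zmat3 transcript (0.866). Double knockout replicate 4 stood apart in the share of the 10 most abundant genes (0.933), and Zmat3 knockout replicate 2 in the Cdkn1a transcript (0.943). Among the named genes, Zmat3 knockout replicate 1 stood apart in 6 (among them Plet1, Plau, Lhx8, Plvap and Ddit4l), double knockout replicate 1 in 2, and Cdkn1a knockout replicates 2 and 3, Trp53 knockout replicate 2, double knockout replicates 2 and 3 and Zmat3 knockout replicate 2 in 1 each.

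The effect of Cdkn1a loss differed between the Zmat3 knockout and Control in 6 lists by camera at the preset correlation. The median difference was 0.09 for G2/M, -0.23 for extracellular matrix, 0.71 for interferon-stimulated, -0.14 for hypoxia and glycolysis, and -0.25 for immediate early genes, and 0.30 for mitochondrially encoded transcripts. For extracellular matrix genes the call was lost without Control replicate 4, where the median was -0.04, and without Zmat3 knockout replicate 3. For hypoxia and glycolysis genes it was lost without any one of Control replicates 1 and 2, Cdkn1a knockout replicate 3, Zmat3 knockout replicates 1, 3 and 4, and double knockout replicates 3 and 4. With an estimated correlation none of these lists passed, the lowest adjusted p being 0.562.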

How the results depend on the processing

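The alternatives that leave out 2 libraries together or 1 library outside a comparison, remove the length trend, rescale Control replicate 3, use edgeR or DESeq2, or include the column letter (the first of 2 in Control) were chosen after the data were seen. Pseudocounts, filters, scaling and block left the gene counts within 1.5 times, except where given here. With the replicate block 10 genes changed in the Cdkn1a knockout. With only the compared libraries, which leaves fewer degrees of freedom, the counts were 0 for the Cdkn1a, 1419 for the Zmat3 and 2071 for the double knockout, 1061 for double against Zmat3 and 5678 for double against Cdkn1a knockout, and Zmat3 in the double knockout was at -0.434 (adjusted p = 0.0527). Without Control replicate 4 and Trp53 knockout replicate 2 together they were 27 for the Cdkn1a knockout, 1042 for double against Zmat3 and 5894 for double against Cdkn1a knockout. For double against Zmat3 knockout the count was 84 with no filter on low values, 467 with the length trend removed and 435 with DESeq2. DESeq2 gave 36 genes for the Cdkn1a knockout and 1 for the interaction. The fall of the Cdkn1a transcript in the Cdkn1a knockout passed the threshold with median-of-ratios scaling (-0.365), without Control replicate 4 alone (-0.388, adjusted p = 0.00636), without both libraries (-0.388), with edgeR (-0.376) and with DESeq2 (-0.368), with adjusted p from 0.0195 to 0.0214 for edgeR and scaling. The correlation of Zmat3 and double knockout effects was 0.847 with no filter, 0.905 with a mean of at least 5 CPM and 0.862 without both libraries. That of Zmat3 and Trp53 was 0.251 with no filter and 0.359 without both libraries, and that of double and Trp53 was 0.360 with a pseudocount of 2, 0.323 with no filter and 0.431 without both libraries. List means turned direction without Control replicate 4, alone or with Trp53 knockout replicate 2: extracellular matrix genes to -0.139 (highest without another library 0.114), ER stress and ATF4 target genes to 0.055 (lowest -0.032) and ribosomal protein genes to 0.106 (lowest -0.151) in the Cdkn1a knockout, and ribosomal protein genes to -0.155 (highest 0.102) in the interaction. The cause of these changes was not tested beyond what the alternatives' construction shows. When each library of a comparison was left out in turn, the counts ranged from 2 to 8 for the Cdkn1a, 2737 to 4033 for the Zmat3, 3628 to 5039 for the double and 5621 to 7513 for the Trp53 knockout, 28 to 189 for double against Zmat3, 2500 to 2926 for double against Cdkn1a and 5735 to 6119 for Trp53 against double knockout, and 0 to 1 for the interaction. Libraries outside a comparison take part through the shared error estimate: without Control replicate 4 the count was 663 for double against Zmat3, 5164 for double against Cdkn1a and 7882 for Trp53 against double knockout, and leaving out any other library outside a comparison moved no count by over 1.5 times. When each library of a comparison was left out, the Cdkn1a transcript ranged from -0.388 to -0.310, and the correlations from 0.856 to 0.899 (Zmat3 and double), 0.283 to 0.374 (Zmat3 and Trp53) and 0.360 to 0.446 (double and Trp53). With 200 changed genes simulated, the test recovered 14 to 26% of the smallest changes. The adjusted threshold is less strict where many more genes change. These shares therefore do not carry over to the Zmat3, double and Trp53 knockouts against Control.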

Other observations

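In the Trp53 knockout, where 6235 of 13024 tested genes changed, members of further lists changed, although none of the lists in this paragraph passed camera, which was not run on skeletal muscle and macrophage markers, with 2 measured members each. The retinoblastoma gene Rb1 fell by 1.55 ± 0.11 on the log2 scale (SE, n = 4), as did the kinase inhibitors Cdkn2c (-0.79 ± 0.07) and Cdkn2d (-0.58 ± 0.09), whereas the cyclin Ccnd2 rose by 1.15 ± 0.14. Of 16 cyclins and kinase inhibitors 6 rose and 5 fell by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.773). Of 22 lysosome and autophagy genes 14 fell and 2 rose by either adjustment, among them the lysosomal hydrolases Gla (-0.92) and Hexa (-0.77), with a camera adjusted p of 0.059. Of 17 YAP/TEAD target genes 3 rose and 6 fell, and 7 fell adjusted over the list alone; the matricellular genes Ctgf (-1.38) and Cyr61 (-0.94) were among those that fell (camera adjusted p = 0.673). The mesenchymal transcription factor Prrx1 (-2.19) and the receptor Pdgfra (-1.55) fell, and of 7 fibroblast and mesenchymal markers 1 rose and 4 fell, 2 and 5 adjusted over the list alone (camera adjusted p = 0.159). Of 8 epithelial markers 5 rose and 2 fell by either adjustment (camera adjusted p = 0.159); summed over all 15 on the list, filtered ones included, they went from between 375 and 562 CPM in Control to between 675 and 817 CPM, and the 14 skeletal muscle markers from between 3.75 and 5.60 CPM to between 19.1 and 22.5 CPM. Other sums fell without overlap: fibroblast and mesenchymal markers to between 2550 and 2930 from 3780 to 4830 CPM, myofibroblast and smooth muscle markers to between 710 and 798 from 1030 to 1250, macrophage and blood cell markers to between 7.06 and 10.7 from 12.7 to 14.5, adipocyte markers to between 32.6 and 34.2 from 39.6 to 49.3, and cartilage and bone markers to between 451 and 470 from 478 to 492. The gap for cartilage and bone markers is small beside the difference in size factors, 0.9366 to 0.9875 here and 0.9461 to 1.0405 in Control. It may not hold after scaling. Of 19 NRF2 target genes, which act in the oxidative stress response, 9 fell and 1 rose by either adjustment, among them Me1 (-0.85), Nqo1 (-0.78) and Srxn1 (-0.70) (camera adjusted p = 0.27).

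In the Zmat3 knockout some cyclins and some of their inhibitors rose. The cyclins Ccnd1 and Ccnd2 rose by 1.05 ± 0.14 and 0.76 ± 0.14, and the inhibitors Cdkn2b and Cdkn2a rose by 0.73 ± 0.11 and 0.69 ± 0.13. Of the 16 cyclins and kinase inhibitors 4 rose and 1 fell by either adjustment (camera adjusted p = 0.291), and of 31 G1/S and DNA replication genes 4 rose and 7 fell (camera adjusted p = 0.58). Of 14 insulin-like growth factor genes 5 rose and 1 fell by either adjustment, including Igfbp4 (1.85), Irs1 (1.20), Dlk1 (1.13) and Igfbp7 (0.73). The camera adjusted p of 0.0182 was lost without Control replicate 4, and the adjusted p was 0.582 with an estimated correlation. Of 17 YAP/TEAD target genes 9 rose and 5 fell, and 10 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.291), with Ptpn14 (1.11), Nuak2 (1.01), Lats2 (0.45) and Axl (0.44) as examples.

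The column names of the Zmat3 and double knockouts also begin with Z1 or Z2, which the labels do not define. Those of the Cdkn1a and double knockouts end in P1 or P2, also undefined, and no comparison took these marks into account. The mean difference of the Hox genes from Control was -0.22 for Z1 and -0.18 for Z2 in the Zmat3 knockout, and -0.35 and -0.26 in the double knockout. The first principal components held 48.0%, 24.0%, 10.1% and 3.82% of the variance.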
